A study of Mus musculus with 64 samples.

How the data were processed

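Biotin-labelled total RNA of bone marrow macrophages was hybridised to 64 Affymetrix arrays, 1 per culture well, in 32 groups of 2 wells. The processing notes name Affymetrix Expression Console 1.1. The deposited values are probe set intensity on the linear scale, normalised between arrays by the authors by a method the labels do not state, and background correction and summarisation are not stated either. This scale was read from the values, which run from 2.49 to 17782 with array medians from 25.6 to 29.0. The series text names empirical Bayes filtering and a network tool for comparing the 6 courses. The numbers of wells, doses, times and strains come from the labels.

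Values were used as log2 of the deposited intensity, with no further normalisation and no filter. Of 35556 probe sets 23099 were in the gene table, 21218 with 1 gene symbol and 1881 with several, and 12457 had no gene. Of those with 1 symbol 21185 were matched to the reference by identifier, and none was renamed. For 1386 genes with more than 1 probe set, the one with the highest mean was kept, which left 18820 genes. Correlation between replicate arrays, across genes, lay between 0.992 and 0.998. No coordinates are given because the array's genome build is not stated.

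Group means were fitted in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, all 64 arrays in 1 fit with 32 residual degrees of freedom, so each group's spread is pooled with the others. Each course was tested by limma's F-test of its 5 differences from 0 h of its strain. Pairs of courses were tested by the same F-test of their 5 differences at matching times. The strain response was tested by that of its 5 differences of changes, and the strains at 0 h by limma's moderated test. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05 with an absolute log2 change of at least 1 at 1 or more times. Direction was taken from the time of the largest absolute change. Gene counts in the report under "larger batch" come from a fit of the 53 arrays of that batch.

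A set of 21 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 genes with the largest rise and the 8 with the largest fall whose arrays both lay beyond both arrays of the group compared, without gene-model names, and up to 4 members per list with the largest change. Values of H2-Ea and Hal in single arrays, and the levels of Ifit1, Cxcl10 and Nos2, were chosen after their values were seen. List shifts were tested with camera with an estimated correlation, adjusted over 630 tests of lists by time and over 168 tests of lists between courses, of which 240 and 70 passed. With a preset correlation of 0.01, 334 and 95 passed. Where several times passed, the lowest adjusted p is printed. Some list members were not analysed here.

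The pipeline was tested on simulated data with 200 changed genes in each of 4 comparisons. Of 50 genes changed by 1.5 log2, 49 (98%) were recovered in each comparison. Of 50 changed by 2, 3 or -2 log2, all were recovered, except 49 at 2 log2 for the strains at 0 h. False calls numbered 0 for IFN-beta, 1 for IFN-beta against IFN-gamma, 4 for the strain response and 0 for the strains at 0 h. Of 20 lists simulated without a shift 0 were called, and the 1 list simulated with a shift was called. The simulated noise was independent between genes and arrays, with no batch and no array that stood apart. These numbers therefore do not cover such features of the real arrays.

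Arrays were parted by the first component of replicate differences over probe sets without a gene, which held 11.4% of that variance, at a score of 0.1. Replicate numbers were not used as a block. Alternatives planned were centring of each array, quantile normalisation, a filter on dim probe sets under the 40th percentile, the mean of a gene's probe sets, every probe set tested, a fit of only the arrays compared, limma with trend and robust settings, no minimum change, a replicate block, and each array left out in turn. Added after seeing the data were the batch as a covariate, only the larger batch, omission of the 5 arrays, changes from 1 h, and the covariate, the omission and the change from 1 h together. The genes that mark BALB/c RNA, over 1.5 log2 higher in every BALB/c group than in every C57BL/6 group except the one tested, were also defined after seeing the data. Genes on several symbols' probe sets and probe sets without a gene were left out of the gene tests.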

Results

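Transcript levels were measured on 64 Affymetrix arrays of macrophages grown from the bone marrow of male BALB/c or C57BL/6 mice in CSF1, the growth factor of this lineage. Each array held labelled total RNA from 1 culture well, and 32 groups of 2 wells each were formed by strain, treatment and time. BALB/c cells received IFN-beta at 10 U/ml, IFN-gamma at 10 U/ml or LPS, a bacterial cell wall component sensed through Tlr4, at 5 ng/ml. C57BL/6 cells received LPS at 50, 5 or 0.5 ng/ml. RNA was collected at 1, 2, 4, 8 and 24 h, and 1 group per strain was collected at 0 h. The labels hold no untreated wells at later times, so every change from 0 h includes whatever changed in culture over that time. Deposited values were normalised intensities with array medians between 25.6 and 29.0, and the number of arrays limits the precision of each value. Unless stated otherwise, each value below is a log2 difference between group means ± SE with n = 2 arrays per group and an adjusted p from limma over 18820 genes. A gene's adjusted p tests all times of its comparison together and is no test of the printed time alone. The wells are cultures from the same preparation as far as the labels tell, so p-values speak for the spread between wells.

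Probe sets without an annotated gene parted the arrays into a larger batch of 53 and a smaller batch of 11, which split 9 groups and held both arrays of IFN-beta at 4 h. After removal of this difference, 5 arrays stood apart from their replicate by over 1.5 log2 in 10 or more genes. These were replicate 1 of LPS 50 ng/ml at 1 h with 80 genes, replicate 2 of LPS 5 ng/ml at 24 h in C57BL/6 with 30, replicate 1 of LPS 0.5 ng/ml at 1 h with 25, replicate 2 of IFN-gamma at 4 h with 14 and replicate 1 of IFN-gamma at 2 h with 12. Of the other pairs none reached more than 7 genes.

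**Figure D1:**
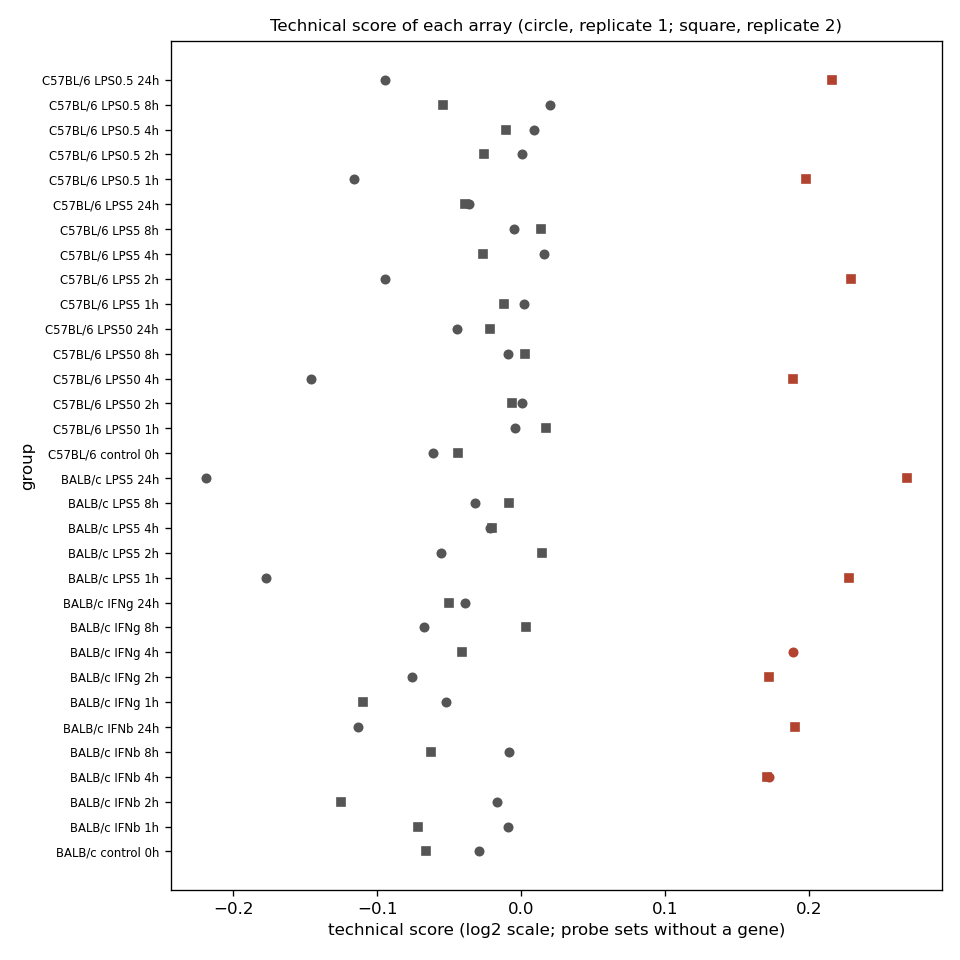
Technical score of each array (x axis, log2, from probe sets without a gene) by group (y axis), with circles for replicate 1, squares for replicate 2 and the smaller batch in red. The 11 arrays of the smaller batch score 0.171 or more and the 53 others 0.0199 or less.

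IFN-beta, a type I interferon, was given to BALB/c cells to follow its transcripts over time. The interferon-inducible GTPase Iigp1 rose 155-fold at 4 h (7.28 ± 0.45, adjusted p = 5e-15), the T cell chemoattractant Cxcl10 rose 83.7-fold (6.39 ± 0.26, adjusted p = 3.2e-24) and the activation antigen Cd69 rose 108-fold (6.76 ± 0.21, adjusted p = 2e-24). The death ligand Tnfsf10 rose 117-fold at the same time (6.87 ± 0.37). Of 28 antiviral genes 27 rose, among them Ifit1 (5.48 ± 0.40 at 4 h), Mx1 (5.41 ± 0.40) and Mx2 (5.16 ± 0.33), and the list was shifted up at all 5 times (lowest adjusted p = 5.2e-05). All 9 GTPases rose, with Gbp5 at 6.42 ± 0.41 and Gbp4 at 6.23 ± 0.33 (list adjusted p = 2.2e-05). Of 14 genes of interferon signalling 9 rose, led by the feedback inhibitors Socs3 (4.38 at 2 h) and Socs1 (3.93 at 2 h), with a list adjusted p of 2.9e-07. Among MHC class I genes 7 of 15 rose, with Psmb10 and Nlrc5 at 2.23 (list adjusted p = 4.2e-05), whereas of 8 MHC class II genes 1 rose, the class II transactivator Ciita (1.03 at 8 h, 0.97 without replicate 1 of 0 h and then under the minimum change), and the list was not shifted (adjusted p = 0.11). Of 26 cell cycle genes 19 fell, including the ribonucleotide reductase subunit Rrm2 (-1.83 at 8 h) and Birc5 (-1.60 at 24 h), and the list was shifted down at 8 and 24 h (adjusted p = 0.00045). The largest falls outside the lists were in Gadd45a, a growth arrest gene (-2.45 ± 0.24 at 4 h), and Uck2, a uridine kinase (-2.42 ± 0.12 at 8 h). Counted from 1 h instead of 0 h the rise was 1.27 for Cxcl10, 0.86 for Mx2 and 0.71 for Ciita. In all, 1490 genes changed, 762 up and 728 down, and adjusted over the list alone the counts of these 6 lists were the same. Within the larger batch 977 genes changed, and there the 4 h group had no array. With the batch as a covariate 149 of the 324 genes that fell most at 4 h were still called fallen, and their median went from -1.25 to -0.97. Of the others 168 kept an adjusted p under 0.05 with a change under 1 log2. Soga1 went from -2.29 to -1.46.

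IFN-gamma, the type II interferon that activates macrophages, was followed in the same strain. Iigp1 rose 152-fold at 24 h (7.24 ± 0.45, adjusted p = 1.2e-16), Gbp4 129-fold at 24 h (7.01 ± 0.33, adjusted p = 1.2e-21) and the chemokine Cxcl9 123-fold at 8 h (6.95 ± 0.43, adjusted p = 3e-16). Socs3 had risen 37.6-fold within 1 h (5.23 ± 0.29). MHC class II genes rose in 7 of 8 cases, with Ciita at 4.12 at 8 h and, at 24 h, H2-Ab1 at 2.52, H2-Eb1 at 2.41 and H2-Aa at 2.35 (list adjusted p = 1.4e-08). MHC class I genes rose in 11 of 15 cases, led by their transactivator Nlrc5 at 2.40 (list adjusted p = 3.3e-06). Of 28 antiviral genes 26 rose (Zbp1 4.11 at 24 h, list adjusted p = 0.002), as did all 9 GTPases (list adjusted p = 0.00011). So did 9 of 14 genes of interferon signalling (Irf1 3.78 at 4 h, 0.19 counted from 1 h, list adjusted p = 6.6e-07). Of 18 co-stimulation and adhesion genes 12 rose and 1 fell (Cd40 3.95 at 4 h, Cd86 3.08 at 24 h, list adjusted p = 6.3e-05). Of 20 chemokine genes 11 rose (list adjusted p = 9e-05). Cell cycle genes fell in 11 of 26 cases (Mcm2 -1.40 at 8 h, list adjusted p = 0.0055). Among macrophage identity genes the fractalkine receptor Cx3cr1 fell 9.22-fold at 24 h (-3.20 ± 0.13, adjusted p = 1.4e-22), while the complement subunit C1qb (3.18) and the Fc receptor Fcgr1 (2.29) rose at 24 h, with 5 of 20 up and 2 down. Clec9a, a receptor of cross-presenting dendritic cells, rose by 4.33 at 24 h, and the other 6 dendritic and erythroid genes did not pass (list adjusted p = 0.075). The inducible nitric oxide synthase Nos2 rose by 4.84 ± 0.86 at 4 h, but its arrays there had an SD of 1.8, and it stood at 3.59 without replicate 2 and at 6.09 without replicate 1. Il1a at 3.91 stood at 1.06 without that replicate 2 and at 6.77 without replicate 1. Il1b at 3.21 (adjusted p = 0.047) stood at 0.12 (adjusted p = 0.09) and 6.30. It also missed the threshold without either array of 0, 1 or 8 h or replicate 2 of 24 h (adjusted p from 0.053 to 0.087), and both genes missed it when only the arrays compared were fitted (adjusted p = 0.1 and 0.58). In total 1010 genes changed, 583 up and 427 down, against 985 in the larger batch alone. Adjusted over the list alone, the counts of the lists named here were the same.

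The 2 interferons were compared at each time. At 24 h Cnn3, an actin-binding calponin, was 33.7-fold lower with IFN-beta (-5.08 ± 0.21, adjusted p = 2.6e-20), Iigp1 21.8-fold lower (-4.45 ± 0.45, adjusted p = 2.1e-08) and Clec9a 20.4-fold lower (-4.35 ± 0.19, adjusted p = 6.3e-19). MHC class II genes were lower with IFN-beta in 7 of 8 cases (Ciita -4.01 at 24 h), and the list differed (adjusted p = 1.9e-07). Antiviral genes were higher with IFN-beta in 16 of 28 cases, with Mx1 at 3.06 ± 0.40 at 2 h and Ifit1 at 3.01 ± 0.40 at 1 h (list adjusted p = 0.0035). Il10, an anti-inflammatory cytokine, was 7.03-fold higher with IFN-beta at 4 h (2.81 ± 0.22, adjusted p = 5.4e-12). GTPases were lower in 7 of 9 cases and chemokines in 10 of 20, higher in 1, with list adjusted p of 0.24 and 0.56 for the mean over the 5 times. Altogether 746 genes differed, 388 higher and 358 lower with IFN-beta, against 598 in the larger batch. With adjustment over the list alone 1 antiviral gene was lower in addition. The responses shared 386 risen genes where 23.6 would be shared by unrelated lists of that size and 253 fallen genes where 16.5 would, and 20 genes moved in opposite directions. Both courses were set against the same 0 h arrays, so their lists are not independent. In 20 simulations with no gene changed and these arrays shared, 0 genes were shared on average, which covers calls from noise alone. With no gene changed hardly any gene is called, so this cannot show how much the shared arrays add to the overlap.

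**Figure D2:**
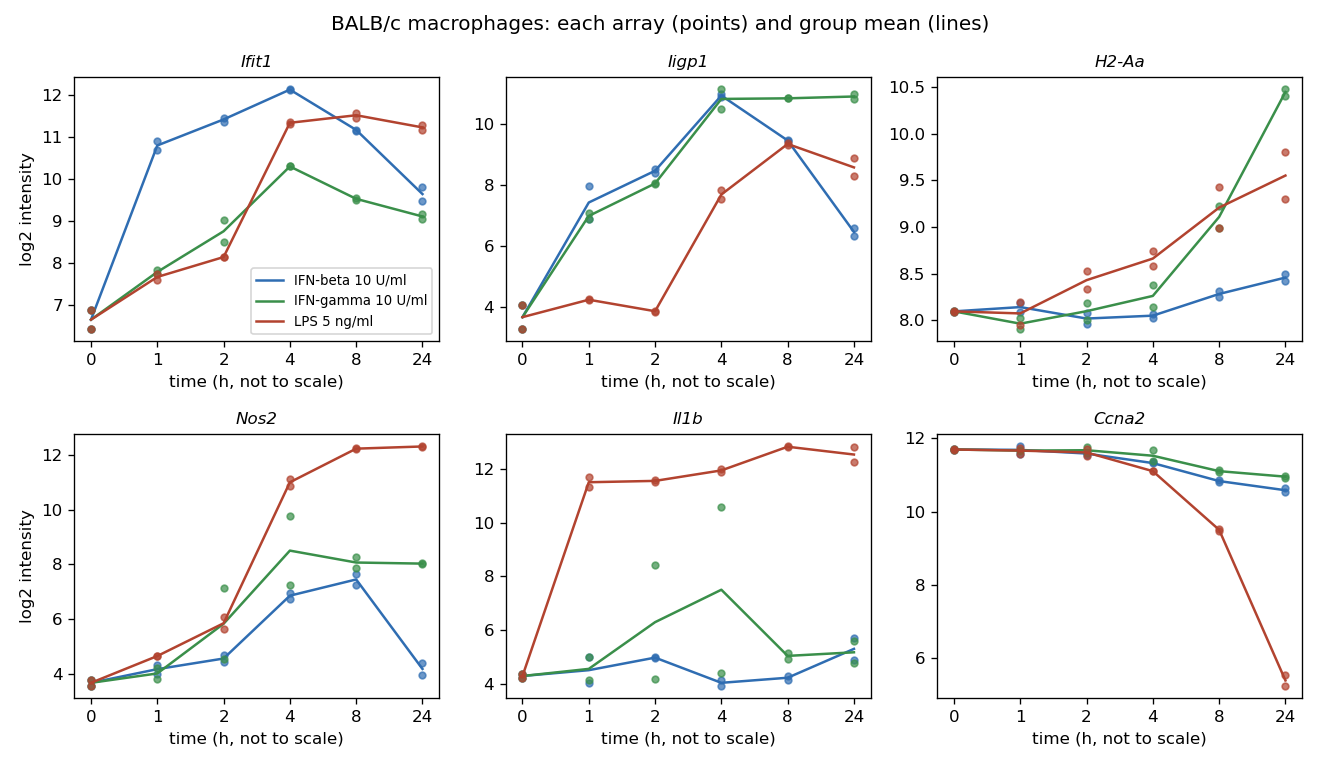
Levels (y axis, log2 intensity) of Ifit1, Iigp1, H2-Aa, Nos2, Il1b and Ccna2 by time (x axis, h) in BALB/c cells after IFN-beta, IFN-gamma or LPS 5 ng/ml, as single arrays with lines through group means. H2-Aa rises by 2.35 with IFN-gamma at 24 h, and Ccna2 fell by 6.30 with LPS at 24 h.

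LPS at 5 ng/ml was followed in the same BALB/c cells. Nos2 rose 401-fold at 24 h (8.65 ± 0.86, adjusted p = 2.6e-13), the pyrogenic cytokine Il1b 369-fold at 8 h (8.53 ± 0.93, adjusted p = 8.4e-10), Il6 240-fold at 8 h (7.91 ± 0.56, adjusted p = 2.9e-17) and Ptgs2, the inducible cyclooxygenase, 203-fold at 8 h (7.67 ± 0.54, adjusted p = 4e-15). The 0 h level of Nos2 lay under the 40th percentile of all log2 values (4.19), so its fold is best read as a lower bound. The siderophore-binding protein Lcn2 rose 262-fold at 24 h (8.04 ± 0.63). The mitotic cyclin Ccna2 fell 78.6-fold at 24 h (-6.30 ± 0.31, adjusted p = 9.2e-21) and the mitotic kinase Plk1 66.8-fold (-6.06 ± 0.29), and all 26 cell cycle genes fell (list adjusted p = 6.3e-05). Inflammatory cytokines rose in 20 of 23 cases (list adjusted p = 5e-05) and chemokines in 18 of 20 (Ccl17 7.53 at 8 h, Cxcl1 6.63 at 1 h, list adjusted p = 1.3e-05). NF-kB pathway and feedback genes rose in 18 of 19 (Nfkbiz 6.15 at 2 h, Tnfaip3 3.79 at 1 h, list adjusted p = 1.9e-09) and effector enzymes in 14 of 17 (list adjusted p = 0.0022). Immediate early genes rose in 16 and fell in 4 of 23 cases, with Egr1 at 4.27 at 1 h, and the list was shifted up at 1 and 2 h (adjusted p = 3.1e-09). Of 22 pattern recognition genes 15 rose and 2 fell (Nod1 3.35 at 8 h, list adjusted p = 0.0035). Of 18 co-stimulation genes 14 rose and 1 fell (Cd40 6.37 at 8 h, list adjusted p = 2.8e-05). Antiviral genes rose in 27 of 28 cases (Ifit1 1.02 at 1 h and 4.87 at 8 h), and the list was shifted up at 4, 8 and 24 h (list adjusted p = 0.0075). MHC class II genes rose in 7 of 8 (list adjusted p = 2.9e-05). Of 20 macrophage identity genes 7 fell and 3 rose, with the mannose receptor Mrc1 at -4.26 and Gas6 at -3.50 at 24 h (list adjusted p = 0.0062). Of 23 genes of cholesterol metabolism 5 rose, led by Ch25h at 1.67 at 24 h (0.44 counted from 1 h, adjusted p = 0.16), and the list was not shifted (adjusted p = 0.066). In total 3231 genes changed, 1401 up and 1830 down, against 3248 in the larger batch, and adjusted over the list alone the counts of these lists were the same. Taken from 1 h instead of 0 h, Il1b rose by 1.32 (adjusted p = 0.64) and Il1a by 1.95 (adjusted p = 0.14), neither of which passed, and Ptgs2 by 1.33 (adjusted p = 0.049). The mean of its probe sets put the fall of Kif18b, a mitotic kinesin, at -3.25 where the brightest one gave -5.38.

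**Figure D3:**
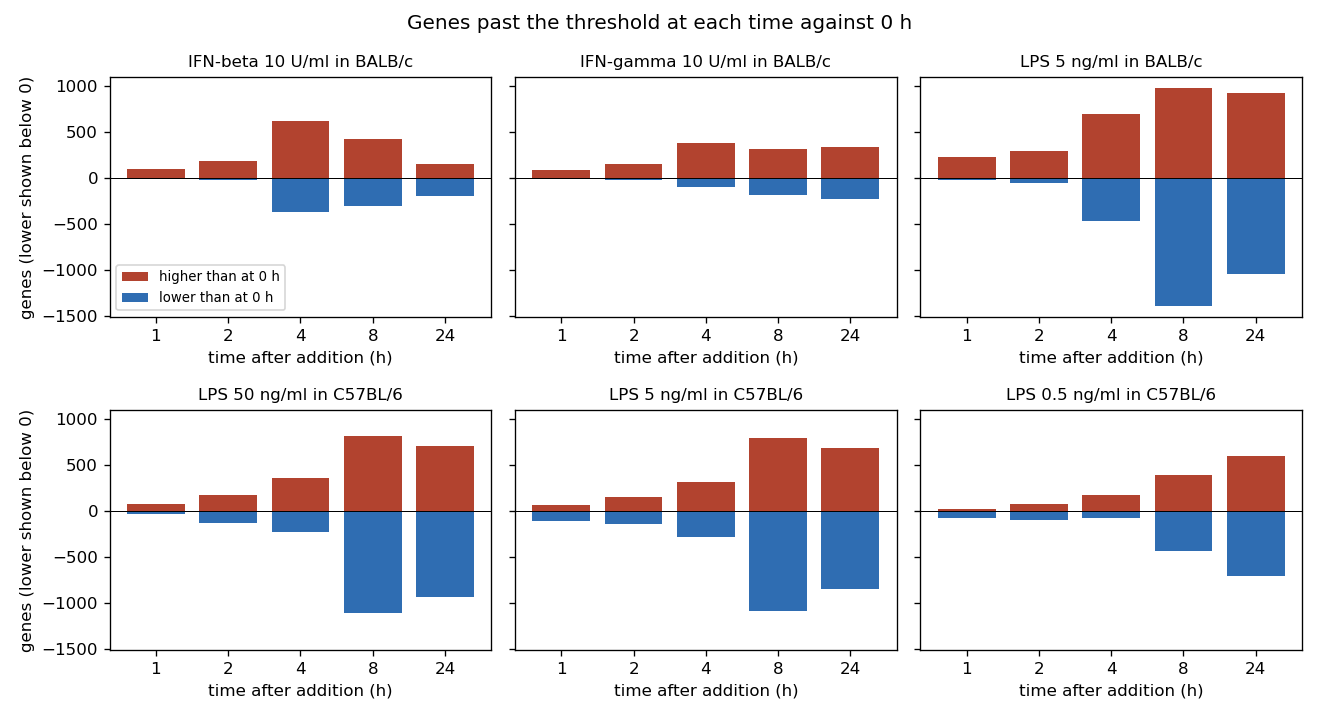
Number of genes (y axis) higher or lower than at 0 h of the same strain by time (x axis, h), for the 6 courses as bars, with lower genes drawn below 0. Genes count at a change of at least 1 log2 and an adjusted p under 0.05 in limma's moderated test of that time alone. With LPS 5 ng/ml in BALB/c 1394 genes are lower at 8 h, and with IFN-beta 305.

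Each interferon was compared with LPS 5 ng/ml in BALB/c. With IFN-beta Il1a was 527-fold lower at 8 h (-9.04 ± 0.79, adjusted p = 5.7e-17) and Il6 237-fold lower (-7.89 ± 0.56, adjusted p = 2.3e-17), while Iigp1 was 24.5-fold higher at 2 h (4.61 ± 0.45, adjusted p = 1.6e-13) and Mrc1 23.9-fold higher at 24 h (4.58 ± 0.15, adjusted p = 2.4e-23). All 19 NF-kB genes were lower with IFN-beta (list adjusted p = 1.6e-06), as were 18 of 23 cytokines, 2 being higher (adjusted p = 5e-04). Cell cycle genes were higher with IFN-beta in 25 of 26 cases (Ccna2 5.19 ± 0.31 at 24 h, list adjusted p = 0.002). Macrophage identity genes were higher in 9 of 20, with 1 lower (list adjusted p = 0.00072). Antiviral genes were higher in 15 and lower in 5 of 28 cases, with no shift of the list in the mean over the 5 times (adjusted p = 0.4). Against 0 h that list was shifted up at all 5 times with IFN-beta, but only at 4, 8 and 24 h with LPS. With IFN-gamma Lcn2 was 332-fold lower at 24 h (-8.37 ± 0.63, adjusted p = 1.9e-15) and the neutrophil chemokine Cxcl1 127-fold lower at 1 h (-6.99 ± 0.46, adjusted p = 7.6e-22). There, 21 of 23 cytokines and 18 of 19 NF-kB genes were lower (list adjusted p = 0.00015 and 1.8e-06). All 26 cell cycle genes were higher (Ccna2 5.55 ± 0.31 at 24 h, list adjusted p = 0.0011). MHC class II genes went both ways, 2 up and 2 down of 8 (list adjusted p = 0.95 for the mean over the 5 times). These counts were the same when adjusted over the list alone. IFN-beta and LPS differed in 2682 genes, 1517 higher and 1165 lower with IFN-beta, and IFN-gamma and LPS in 2559, 1413 higher and 1146 lower. In the larger batch the counts were 2454 and 2582.

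Before treatment the strains differed, with n = 2 arrays in each. The labels name no second preparation of either strain, so strain cannot be told apart from preparation. Hal, the histidine-degrading enzyme, was 125-fold higher in BALB/c (6.97 ± 0.58, adjusted p = 4.7e-12), and the class II chain H2-Ea, which C57BL/6 mice do not make, was 23.4-fold higher (4.55 ± 0.33, adjusted p = 9.6e-14). The C57BL/6 level of H2-Ea, 4.04, lay under the 40th percentile of all log2 values (4.19), so that fold is best read as a lower bound. The C57BL/6 arrays at 0 h held transcripts that LPS induced in BALB/c cells, and whether these came from the untreated cells or from RNA of treated wells was not settled. Nos2 was 117-fold higher there (-6.87 ± 0.86, adjusted p = 1.3e-07, level 10.5 against 3.66), Cxcl10 50.4-fold (-5.65 ± 0.26, adjusted p = 3.7e-19), Ptgs2 46.1-fold (-5.53 ± 0.54, adjusted p = 4.5e-10) and Cd69 34.3-fold (-5.10 ± 0.21, adjusted p = 3.5e-20). For Nos2 the BALB/c level of 3.66 also lay under the 40th percentile of all log2 values (4.19), so its fold is best read as a lower bound. The complement subunit C1qb was 18.2-fold higher in C57BL/6 too (-4.19 ± 0.13, adjusted p = 2.8e-24). Of 23 inflammatory cytokines 11 were lower in BALB/c (Il1b -4.05, Il6 -4.01, list adjusted p = 0.00072), of 20 chemokines 10 were lower and 1 higher (adjusted p = 3e-04), of 17 effector enzymes 5 were lower (adjusted p = 0.0089) and of 20 macrophage identity genes 4 were lower (adjusted p = 1.6e-05). Antiviral genes were lower in 12 of 28 cases (Ifit1 -3.74), and the list missed the threshold with an adjusted p = 0.056 with an estimated correlation. Adjusted over the list alone, 13 antiviral genes and 6 enzymes were lower. Of 13 granulocyte genes Ngp was lower in BALB/c (-1.74), and that list was shifted down (adjusted p = 0.00035). In all 445 genes differed, 207 higher and 238 lower in BALB/c, and 448 in the larger batch. No 0 h array lay in the smaller batch.

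LPS was given to C57BL/6 cells at 3 doses. At 24 h the membrane protein Susd2 rose 74.7-fold with 50 ng/ml (6.22 ± 0.68, adjusted p = 3e-10), 112-fold with 5 ng/ml (6.81 ± 0.68, adjusted p = 3e-12) and 85.9-fold with 0.5 ng/ml (6.43 ± 0.68, adjusted p = 2.8e-10). Lcn2 rose 24.6-, 23.2- and 22.9-fold (4.62, 4.53 and 4.52 ± 0.63). Ccna2 fell 55.3-, 34.9- and 14.7-fold (-5.79, -5.13 and -3.87 ± 0.31). Nos2, high at 0 h, was lower at 2 h by 68.4-, 79.1- and 86.6-fold (-6.10, -6.30 and -6.44 ± 0.86). Cell cycle genes fell in 26, 26 and 25 of 26 cases (list adjusted p = 2.8e-05, 3e-05 and 3e-05) and NF-kB genes rose in 18, 18 and 17 of 19 (adjusted p = 2.7e-07, 3.5e-07 and 5.7e-08). Of 23 cytokines 20, 18 and 9 rose, and 1, 2 and 8 fell, among the latter Il6 (-3.81) and Tnfsf10 (-3.72) at 2 h of 0.5 ng/ml (list adjusted p = 0.0029, 0.0012 and 0.0048, the last for a downward shift at 1 h). Antiviral genes had their largest change upward in 19, 16 and 15 of 28 cases and downward in 8, 11 and 12. The list was lower than at 0 h at 2 h of each dose and at 1 h of the 2 lower doses, and higher at 8 h of each dose (adjusted p = 0.004, 8.2e-05 and 0.00027). For Ifit1 with 5 ng/ml, the level was 10.41 at 0 h, 6.13 at 1 h and 11.95 at 8 h. Macrophage identity genes fell in 6, 8 and 5 of 20 cases, and 2 rose at each dose (list adjusted p = 0.015, 0.0011 and 0.015). Mrc1 stood at -4.04, -3.72 and -2.91 at 24 h. The granulocyte gene Ngp fell by 2.05, 2.14 and 1.36 at 24 h. Altogether 2822, 2689 and 1715 genes changed, 1179, 1107 and 757 up and 1643, 1582 and 958 down, and 2826, 2713 and 1720 did in the larger batch. Adjusted over the list alone the counts of these lists were the same.

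**Figure D4:**
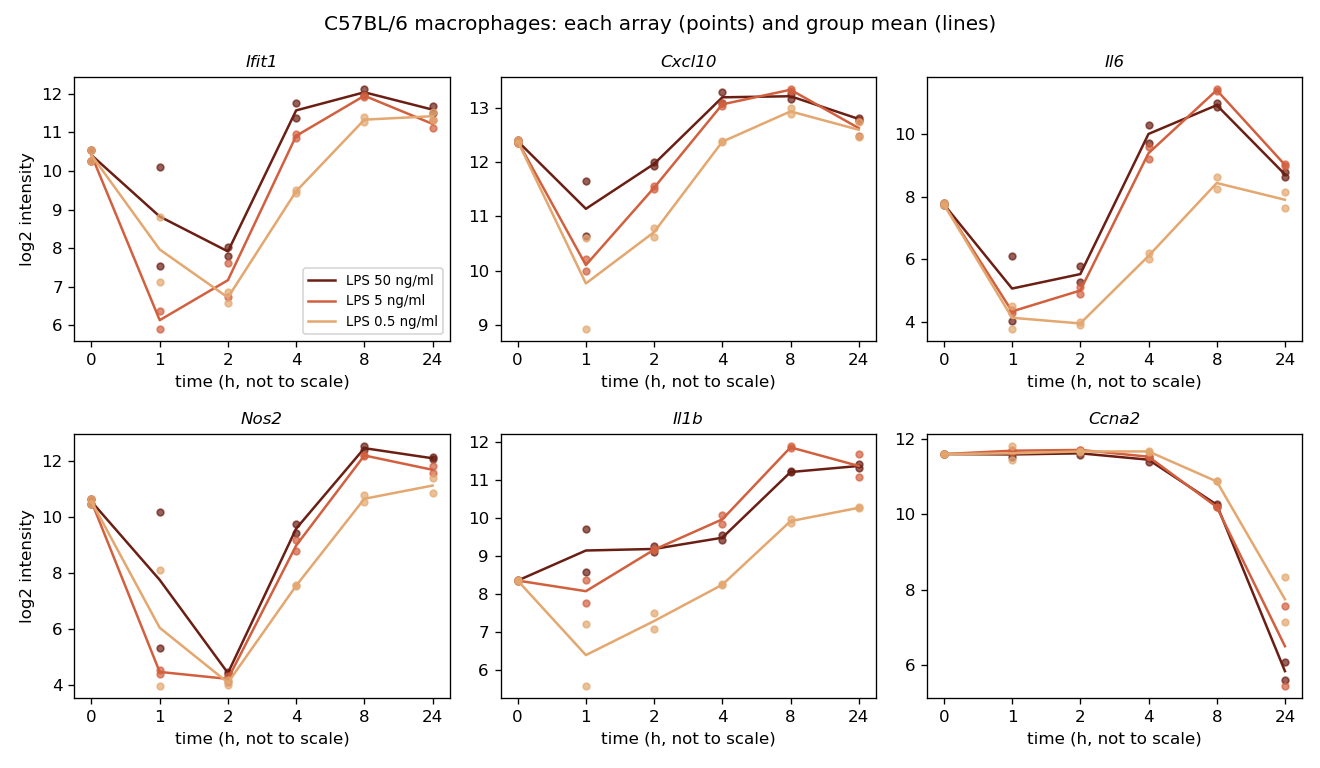
Levels (y axis, log2 intensity) of Ifit1, Cxcl10, Il6, Nos2, Il1b and Ccna2 by time (x axis, h) in C57BL/6 cells after LPS 50, 5 or 0.5 ng/ml, as single arrays with lines through group means. Ifit1 with 5 ng/ml goes from 10.41 at 0 h to 6.13 at 1 h and 11.95 at 8 h.

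Early changes in C57BL/6 depended on the 0 h arrays. Counted from 1 h of the same course, without 0 h arrays, 2746, 2801 and 1961 genes changed with 50, 5 and 0.5 ng/ml, and Nos2 stood at -3.31, -0.25 and -1.95. With the batch as a covariate and without the 5 arrays that stood apart, Nos2 stood at -0.90, -0.15 and -0.06 from 1 h, and with 0.5 ng/ml Il6 stood at 0.09 and Tnfsf10 at 0.24. With 50 ng/ml Lcn2 stood at 3.02 from 1 h. Replicate 2 of 5 ng/ml at 24 h had higher levels of genes that were higher in BALB/c, with H2-Ea at 6.19 against 4.29 in replicate 1 and Hal at 9.21 against 4.74, and its Ccna2 and Plk1 were also higher than in replicate 1. The mean of 12 genes that mark BALB/c lay 1.69 above their C57BL/6 median there, 0.57 above it in replicate 1 of 0.5 ng/ml at 24 h and 0.13 or less in the other arrays.

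Doses were compared with each other at each time. From 0.5 to 5 ng/ml Il6 was 9.74-fold higher at 4 h (3.28 ± 0.56, adjusted p = 5.9e-06), the vasoconstrictor peptide Edn1 10.2-fold higher at 8 h (3.36 ± 0.34, adjusted p = 1.2e-10) and the Th1-promoting subunit Il12a 6.74-fold higher at 8 h (2.75 ± 0.21, adjusted p = 1.6e-11), while the gelatinase Mmp9 was 3.67-fold lower at 24 h (-1.88 ± 0.17, adjusted p = 1.8e-08). Cytokines were higher with 5 ng/ml in 16 of 23 cases, 17 adjusted over the list alone (list adjusted p = 1.6e-05), chemokines in 10 of 20 (adjusted p = 0.00035), co-stimulation genes in 9 of 18 (adjusted p = 0.00012) and immediate early genes in 10 of 23, with 1 lower (adjusted p = 0.0062). Ifit1 was lower with 5 ng/ml at 1 h (-1.83 ± 0.40, adjusted p = 0.001), and stood at -0.99 without replicate 1 of 0.5 ng/ml at 1 h. From 0.5 to 50 ng/ml Il6 was 14.9-fold higher at 4 h (3.90 ± 0.56, adjusted p = 7.5e-07), Il10 10.3-fold higher at 8 h (3.36 ± 0.22, adjusted p = 1.6e-15) and the transcription factor Egr1 7.18-fold higher at 1 h (2.84 ± 0.22, adjusted p = 2.5e-12). There 18 of 23 cytokines (list adjusted p = 2.3e-05), 14 of 23 immediate early genes (list adjusted p = 0.00042) and 8 of 9 GTPases (list adjusted p = 0.03) were higher. List tests between doses were not repeated without the arrays that stood apart. Of 26 cell cycle genes 10 were lower (Ccnb2 -2.0 at 24 h, list adjusted p = 0.025). In total 407 genes differed between 5 and 0.5 ng/ml, 219 higher and 188 lower, and 700 between 50 and 0.5 ng/ml, 378 higher and 322 lower, against 465 and 753 in the larger batch. Except for the cytokines between 5 and 0.5 ng/ml, adjusted over the list alone the counts of these lists were the same.

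Between 50 and 5 ng/ml few genes differed. Il10 was 3.22-fold higher with 50 ng/ml at 8 h (1.69 ± 0.22, adjusted p = 1.2e-05) and the chemokine Ccl8 3.36-fold higher (1.75 ± 0.27, adjusted p = 4e-06). The largest differences were antiviral genes at 1 h, Ifit1 6.44-fold (2.69 ± 0.40, adjusted p = 0.0013), Rsad2 5.32-fold (2.41 ± 0.41, adjusted p = 0.011) and Cmpk2 4.22-fold (2.08 ± 0.33, adjusted p = 0.0045). Without replicate 1 of 50 ng/ml at 1 h Ifit1 still passed at 1.41 (adjusted p = 0.029), whereas Rsad2 at 1.09 (adjusted p = 0.23) and Cmpk2 at 0.96 (adjusted p = 0.11) did not. Without replicate 2 there they stood at 3.97, 3.73 and 3.19, without replicate 1 of 5 ng/ml at 1 h Rsad2 (adjusted p = 0.13) and Cmpk2 (adjusted p = 0.063) missed the threshold, and with only the arrays compared fitted all 3 did (adjusted p = 0.19, 0.28 and 0.26). Of 28 antiviral genes 9 were higher, 15 adjusted over the list alone (list adjusted p = 0.0042). Neither these counts nor the list test were repeated without replicate 1 of 50 ng/ml at 1 h, so they may rest in part on that array. Cyp2s1, a cytochrome P450, was lower with 50 ng/ml at 24 h (-1.28 ± 0.21) and the transcription factor Egr2 too (-1.05 ± 0.21), but without replicate 2 of 5 ng/ml at 24 h they stood at -0.79 and -0.47, without replicate 1 of 50 ng/ml at 24 h at -0.99 and -0.98, and neither passed with only the arrays compared fitted (adjusted p = 0.31 and 0.21). By limma 0 of 26 cell cycle genes passed, with 8 at an unadjusted p under 0.05 (list adjusted p = 0.19). In all 43 genes differed, 33 higher and 10 lower, 72 did in the larger batch and 19 when only the arrays compared were fitted. The count lay between 29 without replicate 2 of 5 ng/ml at 4 h and 147 without replicate 2 of 50 ng/ml at 1 h, 133 of them higher. Without replicate 1 of 5 ng/ml at 24 h it was 121, and there most were lower with 50 ng/ml, 80 against 41 higher.

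The response to LPS 5 ng/ml was compared between strains as the difference of changes from 0 h, BALB/c minus C57BL/6. Here too, strain cannot be told apart from preparation. Nos2 differed 477-fold at 4 h (8.90 ± 1.2, adjusted p = 4.9e-06), Ptgs2 133-fold at 1 h (7.06 ± 0.77, adjusted p = 5.8e-08), Cd69 68-fold at 1 h (6.09 ± 0.30, adjusted p = 1.2e-16) and Cxcl10 60.6-fold at 1 h (5.92 ± 0.36, adjusted p = 2e-14). In BALB/c at 0 h Nos2 lay under the 40th percentile of all log2 values (4.19), so its fold is not exact. The levels after LPS were closer: Cxcl10 at 1 h was 10.4 in BALB/c and 10.1 in C57BL/6, against 6.73 and 12.4 at 0 h, and Nos2 at 4 h was 11 and 8.98. The change from 0 h was higher in BALB/c for 24 of 28 antiviral genes (Ifit1 5.29 at 1 h, list adjusted p = 0.00092) and 12 of 20 chemokines (list adjusted p = 1.8e-06). It was higher for 16 of 23 cytokines with 1 the other way (list adjusted p = 1.4e-05), 14 of 18 co-stimulation genes (list adjusted p = 6e-06) and 14 of 19 NF-kB genes (list adjusted p = 1.3e-05). Falls from 0 h in C57BL/6 enter such differences, as for Cxcl10, and the list tests were not repeated without the 0 h arrays. Adjusted over the list alone the change was higher for 13 chemokines and the other counts were the same. For Gda, a guanine deaminase, the change was lower in BALB/c (-3.05 ± 0.24 at 24 h, adjusted p = 1.4e-13). For Hal the difference of changes was -3.81 ± 0.81 at 24 h (adjusted p = 0.0013). Its levels in the C57BL/6 arrays were 4.74 and 9.21 there, against 4.68 at 0 h, so in C57BL/6 only the array at 9.21 had moved. The difference for Hal stood at -1.58 without that array and at -6.05 without the other. With only the arrays compared fitted, its adjusted p was 0.11. In total 880 genes differed, 616 up and 264 down, against 1004 in the larger batch. Counted from 1 h without the 0 h arrays 709 genes differed, 302 up and 407 down, of which 347 were among the 880, and Nos2 stood at 1.86 (adjusted p = 0.58). With the batch as a covariate and without the 5 arrays as well, 810 differed, 337 up and 473 down.

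Markers of other cells were followed too. With LPS in BALB/c limma called 0 of 9 T and NK cell genes and 0 of 7 B cell genes, where 2 and 0 had an unadjusted p under 0.05 (list adjusted p = 0.72 for both), and 0 of 7 dendritic and erythroid genes, where 1 had (adjusted p = 0.83). The neutrophil collagenase Mmp8 fell among 13 granulocyte genes (-1.88 at 24 h, list adjusted p = 0.63). Of 10 stromal genes Dcn (4.12 at 24 h) and Pdgfrb (3.25 at 8 h) rose and Thy1 fell (-1.10 at 24 h), the last not without either array of 24 h (adjusted p = 0.059 and 0.17), nor with the batch as a covariate (-0.91), with no shift of the list (adjusted p = 0.22). In C57BL/6 Dcn rose by 3.16, 2.65 and 1.53 at 24 h and Pdgfrb by 2.24, 3.29 and 2.10 at 8 h with 50, 5 and 0.5 ng/ml. The stromal list was shifted up from 0.5 to 5 ng/ml (adjusted p = 0.0099) and from 0.5 to 50 ng/ml (adjusted p = 0.0054). Past the threshold there were Pdgfrb (1.37 at 24 h) and Dcn (1.12) at 5 ng/ml and Dcn (1.63) at 50 ng/ml. At 5 ng/ml Dcn stood at 0.97 without replicate 2 of 5 ng/ml at 24 h and at 0.84 (adjusted p = 0.069) without replicate 2 of 0.5 ng/ml, and at 50 ng/ml Pdgfrb (0.92) passed at 1.29 without replicate 1 of 0.5 ng/ml at 24 h. Of 14 housekeeping genes the polymerase subunit Polr2a fell (-1.16 at 8 h, -0.89 counted from 1 h, list adjusted p = 0.24). Adjusted over the list alone these counts were the same.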

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

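Chosen after the result was seen were the tests of a strain difference at 0 h, of the technical batch in the 0 h arrays and in the 5 arrays (in place of counts under the batch covariate, whose outcome the design had fixed for the 0 h arrays and for 2 of the 5 arrays, and which at 81% of the genes kept had left the batch open for the 5), of RNA mixed into the 0 h arrays (set anew after a first form had been run), of BALB/c RNA in 1 array and of splits with each strain's mean removed, the counts from 1 h, the batch covariate, the larger batch alone and the omission of 5 arrays. The way splits were counted and the groups from which the batch coefficient was read were also settled after a first run.

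The response to LPS 5 ng/ml differed between BALB/c and C57BL/6 in 880 genes, by a test of the difference of changes itself. The change from 0 h was higher in BALB/c for Nos2 (8.90), Il1b (7.48), Ptgs2 (7.06), Gbp5 (6.98), Ccl5 (6.77), Cd69 (6.09), Ifi205 (5.93), Cxcl10 (5.92), Il1a (5.78), Edn1 (5.61), Iigp1 (5.31) and Ifit1 (5.29). It was lower for Hal (-3.81), Nrcam (-3.42), Apol7c (-3.12), Gda (-3.05), Cyp2s1 (-2.43), Pttg1 (-2.42), Itga9 (-2.16) and Mtfr2 (-2.15). Of 100 splits that exchanged arrays between the strains at the same time, the real one included, 14 gave as many genes as the real 880, the highest other 1863, so chance was not excluded by them. Such an exchange puts level differences between the strains into the response, a structure of the samples. With each strain's mean removed first, 1 of 100 splits gave as many, the real one, against 531 in the highest other. That second count was chosen after the first was seen, so it does not exclude chance. Every one of these differences includes the 0 h arrays of both strains, and strain cannot be told apart from preparation.

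The 0 h arrays of C57BL/6 held 117 genes at over 1.5 log2 above those of BALB/c, inflammatory transcripts among them. The technical batch of 11 arrays was argued against, as 0 of the 4 arrays at 0 h lay in it. A strain difference before treatment could hold for part of them and stays open: the median of 0 h minus 1 h of LPS 5 ng/ml was 0.724 (quartiles -0.0345 to 2.28), and 57 were over 1 log2 lower at 1 h. RNA of an LPS-treated C57BL/6 group mixed into the 0 h arrays was tested on 37 genes over 1.5 log2 higher at 0 h than at 1 h that hardly moved by 1 h in BALB/c, not on the 117, and needed shares of transcript whose quartiles lay 1.78-fold apart for LPS 0.5 ng/ml at 8 h, but at its median share of 0.413 the 40 genes low in that group would stand at -0.56 (-0.36 at the lower quartile of the share) where -0.09 was measured (quartiles -0.17 to -0.04), which argues against that group. RNA of LPS 50 ng/ml at 8 h, at a share of 0.148, cannot be told apart, with -0.18 expected (-0.13 at the lower quartile) and -0.09 measured (quartiles -0.20 to -0.02), nor can LPS 5 ng/ml at 8 h, at a share of 0.175, with -0.22 expected (-0.16 at the lower quartile) and -0.09 measured (quartiles -0.21 to -0.03), and cells stimulated before 0 h were not tested.

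In 5 arrays 195 genes stood over 1.5 log2 above the replicate, 158 with the batch removed. A well in the state of its best-matching group, or collected at that group's time, was argued against for replicate 1 of LPS 50 ng/ml at 1 h and replicate 2 of IFN-gamma at 4 h. These held 247 and 58 of 309 genes that are 2 log2 or more lower in the best-matching group, and the 309 had a median of only -0.158. With the batch coefficient read from the other groups it was -0.197 over 123 genes, 62 and 58 of them in these arrays. This explanation stays open for the other 3, and a state without such falls was not tested in any of the 5. RNA of another group mixed into the array stays open: 74.1% of the 158 were also higher in the best match (69.1% with the other coefficient), 80 of 80 for LPS 50 ng/ml at 1 h (76 of 80 with the other coefficient and another best match), 13 of 14 for IFN-gamma at 4 h, 19 of 25 for LPS 0.5 ng/ml at 1 h, 5 of 29 for LPS 5 ng/ml at 24 h and 0 of 10 for IFN-gamma at 2 h. The technical batch was argued against for the 2 arrays with 109 of the 195 genes, as 0 arrays of their pairs lay in the smaller batch. For the 3 whose pair the batch splits, with 86 genes, a shift common to split groups was argued against. The 6 other split groups gave a median shift of 0.0202 (quartiles -0.11 to 0.20) against a difference of 1.97 (quartiles 1.71 to 2.47). However, a coefficient read from all groups, these 3 included, left 47 of the 86 over 1.5 log2 and that of the other groups 74. The 3 were among 9 split groups, and in each the replicate lay in the smaller batch, so a link with the batch is not excluded for them. For replicate 2 of LPS 5 ng/ml at 24 h a candidate explanation is BALB/c RNA: all 12 genes that mark that strain were higher in it than in replicate 1, at a median share of 0.113 of the BALB/c 0 h level with quartiles 1.68-fold apart. Shares outside the quartiles differed more. Abhd1 (6.56 against 6.47) and Fah (6.92 against 6.81) were hardly above C57BL/6 at 0 h, and Ifi44l (8.32) was near its BALB/c 0 h level of 8.60. Over the 16 BALB/c groups, all seen before 0 h was taken, the quartile ratio ran from 1.40 to 2.31 and was 2 or more in 2. On these genes replicate 1 of LPS 0.5 ng/ml at 24 h scored 0.57, between the 1.69 of the array tested and at most 0.13 elsewhere.

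Falls at 4 h of IFN-beta, a group with both arrays in the smaller batch, may owe part of their number to that batch. Of 324 genes with their largest fall there, 149 (46%) were called fallen with the batch as a covariate, and their median went from -1.25 (quartiles -1.52 to -1.12) to -0.97 (quartiles -1.22 to -0.72). For 168 of the others the call ended because the change was under 1 log2, with the adjusted p still under 0.05. Of 489 genes with their largest rise there, 400 were still called. No biological explanation was tested.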

How the results depend on the processing

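Added after the data were seen were the batch covariate, the larger batch alone, omission of the 5 arrays and both changes from 1 h. Among the counts of genes, 110 values under planned settings, 218 with 1 array left out and 51 under added settings lay within 1.5 times the reported count. With no minimum change the counts were 7037 for IFN-beta, 5446 for IFN-gamma, 8979 for LPS in BALB/c, 8733, 8728 and 7556 for LPS 50, 5 and 0.5 ng/ml in C57BL/6, 3436 for IFN-beta against IFN-gamma, 7754 and 7920 for IFN-beta and IFN-gamma against LPS, 181 for 50 against 5, 3320 for 5 against 0.5, 4766 for 50 against 0.5 ng/ml, 2943 for the strain response and 1802 for the strains at 0 h, which is the removed threshold itself. With every probe set tested, 35556 in place of 18820 genes, they were 2274 for IFN-beta, 682 for 5 against 0.5 and 1189 for 50 against 0.5 ng/ml. In the larger batch IFN-beta had 977, without any 4 h array, and 50 against 5 ng/ml 72, the cause of which was not tested. With only the arrays compared fitted 50 against 5 ng/ml had 19, with fewer degrees of freedom. With 1 array left out this count ran from 29 to 147, and the cause was not tested. The lone array left in a group is assumed to vary like the other groups. Single genes kept direction and side of the threshold in 10389 values under planned settings, where 150 newly passed and 52 no longer did, in 20558 with 1 array left out, where 95 and 182 did, and in 4697 under added settings, where 47 and 99 did. From 0.5 to 5 ng/ml Plk1 (-1.09) lay between -2.20 without replicate 2 of 5 ng/ml at 24 h and 0.00853 without replicate 1, and the cause was not tested. With changes from 1 h, the batch covariate and the 5 arrays left out together, 15 values of 13 genes changed sign: with LPS 50 ng/ml Gbp2 (0.22), with 0.5 ng/ml Rsad2 (0.524), Cmpk2 (0.0336), Irf7 (0.17), Gbp2 (0.475), Gbp5 (0.772), Iigp1 (0.751), Gbp3 (0.329), Il6 (0.0888), Tnfsf10 (0.238), Cxcl9 (0.355) and Ccl5 (0.546), and in the strain response Cish (-0.309), Gbp3 (-0.128) and Mmp14 (-0.00272). This setting removes the 0 h arrays, and which of its 3 changes turned each sign was not tested. Arrays share only a replicate number: over 120 pairs of groups per strain, deviations of same-numbered arrays correlated at -0.47 to 0.55 in BALB/c (median 0.0027) and -0.09 to 0.46 in C57BL/6 (median 0.006), and on average 10 of 16 and 14 of 16 groups lay closer to their own number, a hint from the data and not from the design. With a replicate block, the paired setting, the counts in the order above were 1491, 1009, 3231, 2822, 2691, 1715, 745, 2684, 2559, 44, 410, 702, 899 and 463, and 237 and 69 list tests passed. Scaling moved array medians by at most 0.0909 log2. Signal over background limits dim genes, of which a filter removed 4936 and kept 13884.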

Other observations

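The way splits were counted was settled after a first run, no other of the tests in this part was chosen after its result was seen, and the shared genes were counted without a test of their number.

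Responses to interferon and to LPS in BALB/c overlapped. IFN-beta and LPS 5 ng/ml shared 482 risen genes where unrelated lists of that size would share 56.7 and 517 fallen genes where they would share 70.8, and 111 genes moved in opposite directions. IFN-gamma and LPS shared 404 risen (43.4) and 329 fallen genes (41.5), with 85 opposite. Among doses in C57BL/6, 50 and 5 ng/ml shared 998 risen (69.3) and 1387 fallen genes (138), with 22 opposite, 5 and 0.5 ng/ml 660 (44.5) and 867 (80.5), with 45, and 50 and 0.5 ng/ml 641 (47.4) and 845 (83.6), with 63. Courses of 1 strain were set against the same 0 h arrays, so their lists are not independent. In 20 simulations with no gene changed and these arrays shared, 0 genes were shared on average, which covers calls from noise alone. What the shared arrays add to the overlap of changed genes was not simulated. Between the strains, with separate 0 h arrays, LPS 5 ng/ml shared 935 risen (82.4) and 1243 fallen genes (154), with 75 opposite.

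At 24 h of the C57BL/6 courses the scavenger receptor Marco rose by 4.33, 3.92 and 3.86 with 50, 5 and 0.5 ng/ml of LPS (adjusted p = 3.4e-13, 7.9e-13 and 5.1e-12), and the class I gene H2-Q6 by 3.26, 3.31 and 2.48 (adjusted p = 2.5e-12, 9.7e-14 and 2.1e-10). Over all 64 arrays the first 3 principal components held 37.1%, 17.4% and 10.7% of the variance.

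Splits exchanged arrays between 2 courses at the same time, 100 per comparison with the real one included. A split can keep the real arms at some of the times, so its count can lie close to the real one. Narrow margins can come from this alone, so their width says nothing for or against chance. The real split alone gave as many genes (1 of 100) in each of 6 comparisons, and chance was not firmly excluded. In 3 of them the real count with 1 array left out fell below the highest other split. These were IFN-beta against IFN-gamma, LPS 50 against 5 ng/ml and 5 against 0.5 ng/ml. Those splits were counted with all arrays, so the fits are unlike, and no firm exclusion rests on the margins. The real count and the highest other were 746 and 737 for IFN-beta against IFN-gamma, 2682 and 2620 for IFN-beta against LPS, 2559 and 2526 for IFN-gamma against LPS, 43 and 41 for LPS 50 against 5 ng/ml, 407 and 391 for 5 against 0.5 ng/ml and 700 and 681 for 50 against 0.5 ng/ml.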
